A study of Glycine max with 26 samples.

How the data were processed

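Soybean seeds were profiled on single-colour oligonucleotide arrays hybridised with biotin-labelled cRNA made from 2.5 µg total RNA, per the labels' protocols. Plants grew at 350 µmol m-2 s-1, 25 °C and 75% humidity, per the labels. The deposited values are log2 signals per probe set, background-corrected and normalized with GCRMA by the authors, per the submitters' processing notes. The GCRMA version and any filter on probe sets are not given in the sources used here, and the log2 scale was read from the range of the values. GCRMA sets low signals to a floor that differed between arrays, so that changes of weakly expressed genes can be compressed. The table held 16383 probe sets, all with IDs of the soybean part of the array. It was in ID order and its last IDs belonged to the second of 2 series of soybean IDs, so soybean probe sets with later IDs may be missing from it, and every count applies to this table only. Other probe sets of the array were not analysed here. Probe sets for other organisms were therefore not tested.

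Samples were grouped by the time in their labels, 13 times with 2 replicates each. A replicate is a pool of 8 seeds from 3 plants. The labels do not say whether the replicates of a time came from different plants, so p-values measure the spread between these samples, which may in part be technical. Over the 11481 probe sets with a mean log2 signal above 4, the 2 replicates of a time held no identical values and correlated at r of 0.977 to 0.994. The numbers of the array batches and of the replicates were crossed at 2 times.

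Gene names came from the platform annotation used here, which gave 1 symbol for 5002 probe sets, several for 217 and none for 11164. Of the 5002, 4989 were found in a RefSeq gene table of assembly Glycine_max_v4.0, which changed 0 symbols. A symbol that was only a locus number took the first synonym of that table as its name where there was one. Symbols can be old, and no coordinates are given because the build behind the array is not given in the sources used here. A probe cluster here is the set of probe sets whose IDs share their first number, which can hold different genes, as for LHY and CAB3. For 1 probe set per cluster or gene, that with the highest mean signal was taken. Gene functions are textbook background, since the annotation held symbols without descriptions.

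Probe sets with a mean log2 signal above 4 over all arrays were tested, 11481 of the table (70.1%). All tests used limma 3.58.1 in R 4.3.3, with lmFit and eBayes on log2 values and Benjamini-Hochberg adjustment at 0.05. The rhythm test was the moderated F of a cosine and a sine of 24 h with linear time as a covariate, on all 26 arrays. The linear trend was the time term of the same fit. Any difference between times was a moderated F over the 13 times, and subjective dawn was compared with subjective dusk by a contrast of 6 arrays against 4 in the fit of 13 times. The first and second cycle were compared by an interaction fitted on the arrays from 24 to 68 h, among the rhythmic probe sets. Periods were scanned from 18 to 30 h in steps of 0.25 h. Gene lists were compared by two-sided Fisher's exact tests on rhythmic probe sets and by camera on the dawn and dusk contrast. The 16 lists fixed before the data were examined took genes by patterns in symbols and synonyms; because the annotation had no descriptions, 18 further lists were written by symbol.

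Named genes followed a rule written before the data were examined: core clock members by smallest p; up to 12 named rhythmic probe sets of largest amplitude whose peak times on the replicates differed by at most 3 h; up to 3 rhythmic members of each list, or its member with the smallest p; and the largest named changes of the dawn and dusk contrast and of the trend past the threshold, of which there were none. The rule asked for a gene description, and a symbol or synonym that was no locus number was used in its place.

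The steps were tested on simulated values with the real means and spreads of 11481 probe sets. Noise was drawn independently for each probe set and array, without any structure shared between probe sets. The rates below may therefore not hold for the real arrays. Rhythms with an amplitude of 0.3 log2 were recovered for 78% of 50 probe sets, of 0.5 for 92% and of 1 for 98%, and false calls made up 8% of all calls. For the dawn and dusk contrast, changes of 0.5 were recovered for 52% and of 1 for 94%. For the linear trend, changes of 0.5 over 48 h were recovered for 46% and of 1 for 90%. For any difference between times, amplitudes of 0.5 were recovered for 66% and of 1 for 98%.

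Alternatives covered the filter, another normalization, the moderation of variances, the replicate and the array batch as blocks, arrays left out, other periods and harmonics, list thresholds and covariates. The array batch, periods beyond 22 and 26 h, the maturation and array median covariates, the replicate block for gene lists and peak times, 1 probe set per probe cluster and the count without probe sets marked as shared were added after seeing the data. The lists by symbol were also added later, after the values and the gene symbols had been looked at and before any value was tested.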

Results

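Gene expression was measured in whole soybean seeds, seed coats included, of the cultivar Williams 82 at 5 weeks after flowering. The plants had been entrained to cycles of 12 h light and 12 h dark and then stayed in constant light at 25 °C. Seeds were taken every 4 h from 24 h to 72 h after the start of constant light, where 24 h is subjective dawn, so that 2 whole cycles of 24 h were covered. Each of the 13 times had 2 replicates, and each replicate pooled 8 seeds from 3 plants, which gave 26 single-colour oligonucleotide arrays. The values are log2 signals per probe set, as normalized by the authors. The probe sets of the table ran from the lowest log2 signal of an array, between 1.54 and 3.02, to a highest of 16.79, and array medians lay between 6.08 and 6.47. Across the probe sets with a mean log2 signal above 4, arrays correlated with each other at r of 0.972 to 0.996. The median over arrays of one time, 0.989, was the same to 3 digits as that over arrays of different times. The number of arrays limits the precision of every value. The lowest signal of the arrays split them into 13 arrays with a low floor and 13 with a high floor, 1 of each at every time, and values with this array batch as a block are given beside the results.

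The study's title asks which seed transcripts follow the circadian clock. In constant light, a 24 h fit called rhythms for transcripts of a lipoxygenase gene, of chloroplast proteins and of many genes without a descriptive name. Most of them were highest in the late subjective night. The calls of the lipoxygenase gene and of some chloroplast genes ended when certain single arrays were left out. The largest rhythm was that of LOX7, a lipoxygenase, an enzyme that oxidizes polyunsaturated fatty acids. The stronger of its 2 rhythmic probe sets averaged 8.33 ± 0.77 (SD, n = 4) in log2 signal in the late subjective night, at 44 and 68 h, and 6.71 ± 1.13 (SD, n = 4) at subjective midday, at 32 and 56 h. CHS8, a chalcone synthase, the first enzyme committed to flavonoid synthesis, ran the other way, with 8.49 ± 0.75 (SD, n = 4) in the late night and 9.69 ± 0.78 (SD, n = 4) at midday. A limma fit of a 24 h cosine and sine with linear time called 138 of 11481 probe sets tested (1.2%) at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 1186, where chance alone gives 574. These counts apply to the 16383 probe sets of the table used here, which was in ID order and may lack soybean probe sets with later IDs. The 138 probe sets belonged to 107 probe clusters, and 84 carried 1 gene symbol, for 69 genes. With the array batch as a block the count was 168, which held all 138. As every time had 1 array of either batch, the block left the fitted amplitudes unchanged, so this overlap is no independent check of the calls. Within the low floor arrays alone no probe set passed, with 554 at an unadjusted p under 0.05. Within the high floor arrays alone 1509 had an unadjusted p under 0.05 and 42 passed, 31 of them among the 138. The count fell to 72 without 44h replicate 1, to 77 without 24h replicate 2, to 78 without 32h replicate 1 and to 91 without 32h replicate 2. It rose to 258 without the linear time term and to 232 after another quantile normalization, and fell to 76 without the filter on low signals and to 28 when 24 h and 12 h harmonics were tested together.

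**Figure D1:**
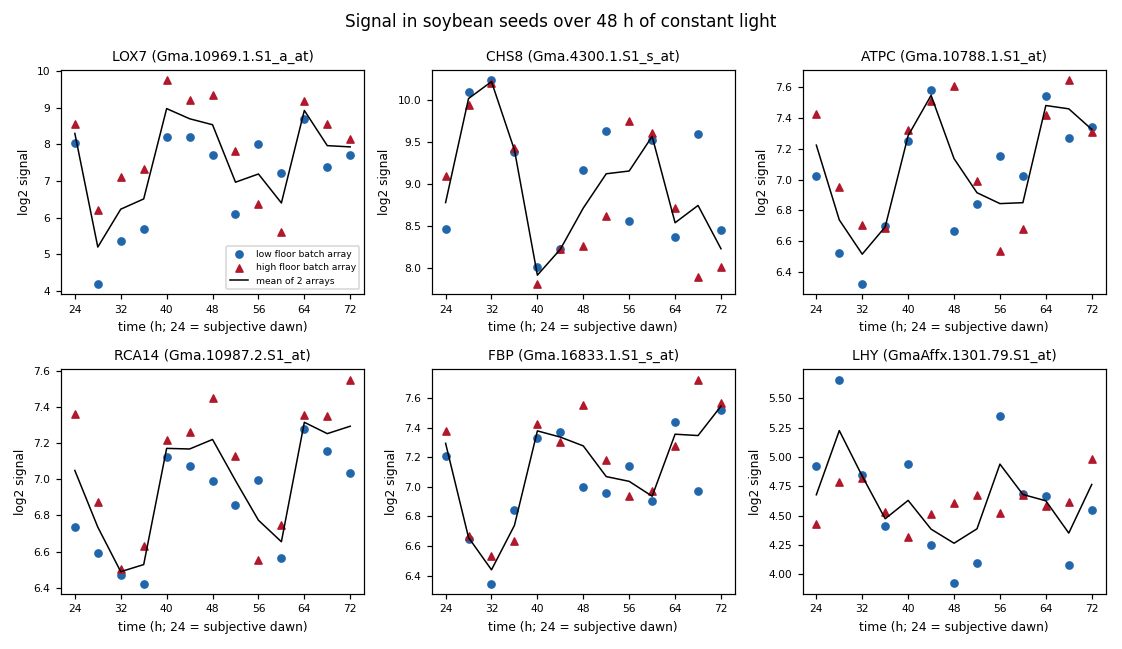
Log2 signal of LOX7, CHS8, ATPC, RCA14, FBP and LHY against time in constant light in hours, with 1 point per array (circles for the low floor batch, triangles for the high floor batch) and a line through the mean of the 2 arrays of a time; each panel has its own log2 axis. LOX7 has a fitted peak at 19.3 h after subjective dawn and CHS8 at 7.58 h, while LHY did not pass the test for a rhythm.

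Among the rhythmic genes with a name, LOX7 had a fitted amplitude of 1.34 ± 0.29 (SE) log2, a 6.41-fold change from trough to peak, with a peak 19.3 h after subjective dawn (limma adjusted p = 0.0412). Its other rhythmic probe set had an amplitude of 1.23 ± 0.26 (SE; limma adjusted p = 0.0325). The amplitude of CHS8 was 0.74 ± 0.16 (SE) with a peak at 7.58 h (limma adjusted p = 0.0325). The IDs of the probe sets of CHS8, FBP, LHCP, ELIP and both of LOX7 mark them as shared between transcripts, as did those of 51 of the 138 (37.0%) and 21% of all tested. LHCP, a name used for light-harvesting chlorophyll proteins, had an amplitude of 0.53 ± 0.12 (SE), and ELIP, an early light-induced protein of the thylakoid, one of 0.50 ± 0.11 (SE). ATPC, named for the gamma subunit of the chloroplast ATP synthase, had an amplitude of 0.42 ± 0.07 (SE; limma adjusted p = 0.00444). FBP followed with 0.34 ± 0.06 (SE), RCA14, a Rubisco activase, with 0.33 ± 0.06 (SE), and RCAALPHA, another Rubisco activase, with 0.30 ± 0.06 (SE). SIP1-6 at 0.36 ± 0.08 (SE), GH at 0.36 ± 0.06 (SE) and PRP3 at 0.35 ± 0.07 (SE) completed the named genes with the largest amplitudes. The probe set of PRP3 comes from the same probe cluster as those of LOX7. The peaks of these genes other than CHS8 lay between 17.9 h for SIP1-6 and 21.1 h for RCAALPHA. The calls of ATPC, FBP, GH and RCA14 held whichever single array was left out. That of PRP3 ended without 24h replicate 2 or 44h replicate 1, and that of RCAALPHA without 24h replicate 2, 32h replicate 1, 44h replicate 1 or 60h replicate 1. The calls of LHCP ended without any of 19 arrays, those of ELIP and of the first LOX7 probe set without any of 18, SIP1-6 of 13, CHS8 of 12 and the second LOX7 probe set of 7.

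The only named gene of the circadian oscillator that was tested gave no rhythm that passed. LHY, a morning-expressed MYB factor of the oscillator, was the single gene of the core clock list with probe sets above the signal filter, and both of its 2 probe sets were weak. The stronger averaged a log2 signal of 4.63 with an amplitude of 0.20 ± 0.10 (SE; limma adjusted p = 0.711). LCL3, the list's other member on the table, lay below the filter. The count was 0 of 2 over all probe sets tested, 0 adjusted over the list alone, 0 at an unadjusted p under 0.05 and 0 with the array batch as a block. Other oscillator genes were not named among the probe sets of the table used here, which may lack part of the array's soybean probe sets. As 11164 probe sets of the table carried no gene symbol, other oscillator genes may also be among them without a name.

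Chloroplast genes held more rhythmic probe sets than other annotated genes, though the excess did not pass the test when each probe cluster counted once. Storage protein, oil, maturation and ribosomal protein genes held none, but their lists were too small to show a lack of rhythm. Even the maturation list, with 32 probe sets, was set against only 84 of 3845 other annotated probe sets that were rhythmic. Of the 18 probe sets in the list of chloroplast and tetrapyrrole genes, 6 passed, namely ELIP, 3 of RCA14, RCAALPHA and PSAD, a subunit of photosystem I. ATPC and LHCP, named above as rhythmic, were not in this list, which was matched by symbol alone. By Fisher's exact test, two-sided, against 78 of 3859 other annotated probe sets, the adjusted p was 2.35e-05 over 18 lists by symbol. Adjusted over the list alone 11 probe sets passed, and with the array batch as a block 8. The 3 probe sets of RCA14 and that of RCAALPHA, 4 of the 6, came from one probe cluster and are not independent in this test. With 1 probe set per gene 4 of 14 passed, against 61 of 3268 others (adjusted p = 0.00218 by Fisher's exact test). With 1 per probe cluster 2 of 12 passed, against 53 of 3225 others (adjusted p = 0.302 by Fisher's exact test). That share was still the higher one, but with so few probe clusters the enrichment did not pass. Over all 18 probe sets it also did not pass without 24h replicate 2 (2 probe sets, adjusted p = 0.394 by Fisher's exact test) or 44h replicate 1 (2, adjusted p = 0.336). The same held without 48h replicate 2 (3, adjusted p = 0.0577) or 60h replicate 1 (2, adjusted p = 0.678). The 18 lists by symbol were written after the values and the gene symbols had been looked at and before any value was tested.

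Among the other lists by symbol, 2 of 10 lipoxygenase probe sets were rhythmic, both of LOX7 (adjusted p = 0.168 by Fisher's exact test), and 5 adjusted over the list alone. The list of starch, sucrose and sugar transport genes had 1 of 12, FBP, the flavonoid pathway list 1 of 30, CHS8, and the auxin signalling list 1 of 9, GH, which was matched by its symbol alone. No probe set passed among 25 of storage proteins and inhibitors, 20 of oil and lipid synthesis, 9 of PEP carboxylases and their kinases, 16 of antioxidant enzymes and 7 of light signalling. Nor did any pass among 30 of MYB factors, 36 of bZIP factors, 20 of WRKY and NAC factors, 19 of aquaporins and 19 of glutathione transferases. The lists of GASA peptides with 10, nodulins with 4 and calmodulins and 14-3-3 proteins with 18 had none either. Members of these lists with the smallest p included the glutathione transferase GSTU37 with an amplitude of 0.30 ± 0.07 (SE; limma adjusted p = 0.0698), the protease inhibitor BBI-2 with 0.64 ± 0.18 (SE; limma adjusted p = 0.164), and MYB93 with 0.12 ± 0.04 (SE; limma adjusted p = 0.193). For NAC6 the amplitude was 0.37 ± 0.11 (SE), for BZIP95 0.16 ± 0.05 (SE), for GASA3 0.17 ± 0.05 (SE), for PIP2-1 0.12 ± 0.04 (SE), for PPCK2 0.12 ± 0.04 (SE), for Ep 0.13 ± 0.05 (SE), for N-26 0.16 ± 0.08 (SE) and for GF14C 0.10 ± 0.03 (SE).

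None of the 16 lists fixed before the data were examined held more rhythmic probe sets than other genes by Fisher's exact test. In the list of flavonoid and isoflavonoid synthesis 1 of 11 probe sets passed, CHS8, while 5 passed adjusted over the list alone and 3 with the array batch as a block, where this list was enriched. The photosynthesis list had 0 of 2, and 2 adjusted over the list alone; its leading member was the chlorophyll a/b-binding protein gene CAB3, with an amplitude of 0.26 ± 0.07 (SE; limma adjusted p = 0.188). The clock output list had 0 of 2, and 1 adjusted over the list alone, with COL10, a CONSTANS-like gene, at 0.23 ± 0.07 (SE; limma adjusted p = 0.218). The housekeeping list had 0 of 5, and 1 adjusted over the list alone, with the tubulin gene TUBB3 at 0.25 ± 0.07 (SE). No probe set passed in the lists of seed storage proteins with 13, of oil and fatty acid synthesis with 11, of seed maturation and desiccation with 32, of heat shock and chaperones with 12, of cold and redox with 7, of ribosomal proteins with 6, of seed coat with 2 and of cell division with 1, nor adjusted over each of these lists alone. Their leading members were the glycinin gene GY3 at 0.29 ± 0.10 (SE), the desaturase FAD2-2 at 0.26 ± 0.08 (SE), the maturation protein PM23 at 0.14 ± 0.04 (SE), HSF-33 at 0.25 ± 0.08 (SE), DREB2A2 at 0.22 ± 0.09 (SE), the ribosomal protein RPS6 at 0.07 ± 0.03 (SE), the hydrophobic seed protein HPS at 0.19 ± 0.07 (SE) and CDC48 at 0.02 ± 0.04 (SE). The lists of carbon fixation, of starch and sucrose metabolism and of auxin and growth matched no annotated probe set.

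Peak times of the rhythmic probe sets fell at opposite ends of one axis. The bin centred on subjective midnight held 110 of the 138 (79.7%), the midday bin 18, the dawn bin 9 (6.52%) and the dusk bin 1 (0.725%). Of all probe sets tested, 20.3% peaked in the midnight bin and 43.9% in the midday bin. Between 18 and 22 h lay 117 peaks (84.8%), against 18.6% of all tested, and between 5 and 9 h lay 18. The median amplitude was 0.33 log2, from 0.15 to 1.34, the median change from trough to peak was 1.58-fold, and 15 probe sets changed by over 2 times.

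**Figure D2:**
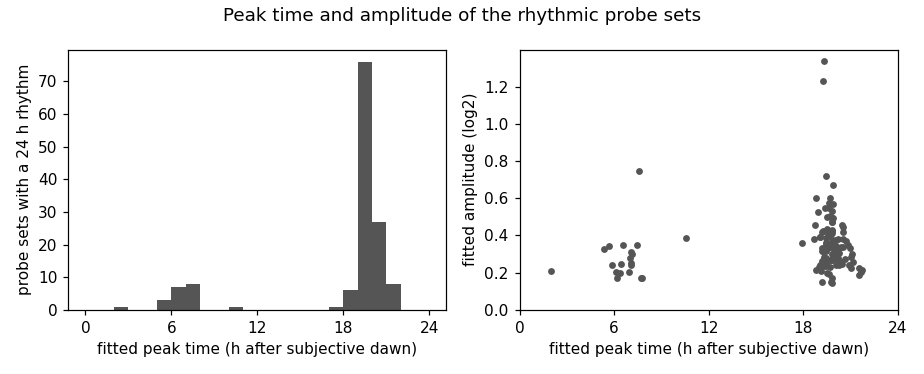
Left, number of rhythmic probe sets by fitted peak time in hours after subjective dawn, in bins of 1 h. Right, fitted amplitude in log2 against peak time in hours, 1 point per probe set; 117 of the 138 peaks lie between 18 and 22 h, and the points above 1.2 are the 2 probe sets of LOX7.

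No gene drifted steadily over the 48 h in a way that passed the test. The limma test of linear time called 0 of 11481 probe sets, with 612 at an unadjusted p under 0.05, of which 358 rose and 254 fell, and a smallest adjusted p of 0.108. The count was also 0 with the array batch as a block and within the low floor and the high floor arrays. It rose above 0 with the replicate as a block, without the 24 h terms and with some arrays left out. LOX7, CHS8 and LHY had limma adjusted p of 0.995, 0.986 and 0.995 for the linear term.

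With no assumption about the shape of the time course, few genes differed between times. GASA4, of a family of gibberellin-regulated peptides, passed (limma adjusted p = 0.0450), with 4 probe sets that do not carry exactly 1 gene symbol. GASA4 was named after its values were seen. The fitted 24 h rhythm of GASA4 itself did not pass (limma adjusted p = 0.546). The limma test over the 13 times thus called 5 of 11481 probe sets, 3 of them among the rhythmic ones, with 860 at an unadjusted p under 0.05. With the array batch as a block the count was 35. It changed by over 1.5 times without any single array except 52h replicate 2, 60h replicate 1 and 60h replicate 2, and reached 59 without 48h replicate 1.

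No single gene passed the test between subjective dawn, at 24, 48 and 72 h, and subjective dusk, at 36 and 60 h. Simulated changes of 0.5 log2 with independent noise were recovered for 52% of probe sets in this test. The limma contrast called 0 of 11481 probe sets, and its smallest adjusted p was 0.513. At an unadjusted p under 0.05 there were 621, of which 424 were higher at dawn and 197 at dusk. With the array batch as a block the count stayed 0, with a smallest adjusted p of 0.0852, and without 60h replicate 1 it was 1. Among named genes, chosen after their values were seen, the smallest p belonged to GOLS, a galactinol synthase gene, with 5.64 ± 0.42 (SD, n = 6) at dawn and 6.84 ± 0.32 (SD, n = 4) at dusk, a difference of -1.19 ± 0.26 (SE) log2 (limma adjusted p = 0.513). For RCA14 the difference was 0.60 ± 0.14 (SE), for FBP 0.53 ± 0.13 (SE), for BG7S-2, a basic 7S globulin gene, -1.23 ± 0.31 (SE) and for RCAALPHA 0.57 ± 0.15 (SE), and none passed. Of the 138 rhythmic probe sets, 121 had a higher mean at dawn, which follows largely from their peak times, fitted on the same arrays.

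As groups, maturation genes were higher at dusk, and chloroplast and lipoxygenase genes at dawn, by limma's camera with its preset correlation of 0.01, and of 2 lists of flavonoid genes 1 was higher at dusk. The 32 probe sets of seed maturation and desiccation had a median difference, dawn minus dusk, of -0.23 log2 (camera adjusted p = 1.6e-09; adjusted p = 0.347 with an estimated correlation). The 11 of the fixed flavonoid and isoflavonoid list had a median of -0.06 (camera adjusted p = 0.00206; adjusted p = 0.347 with an estimated correlation). The 30 of the flavonoid pathway list by symbol had a median of the opposite sign, 0.07, and did not pass (camera adjusted p = 0.743; adjusted p = 0.904 with an estimated correlation). The 18 of chloroplast and tetrapyrrole genes had a median of 0.22 (camera adjusted p = 1.81e-05; adjusted p = 0.423 with an estimated correlation). The 10 of lipoxygenases had a median of 0.49 (camera adjusted p = 3.67e-04; adjusted p = 0.423 with an estimated correlation). None of these 4 calls held with an estimated correlation. All held with the array batch as a block, but that fit kept the preset correlation and so has the same limit. The other 6 fixed lists and 16 lists by symbol that had at least 3 probe sets did not pass.

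Rhythmic genes had smaller amplitudes in the second cycle, but few differences passed a test. From 24 to 44 h the median amplitude of the 138 probe sets was 0.42 log2, and from 48 to 68 h it was 0.25. The median ratio, second over first, was 0.580, with quartiles of 0.439 and 0.763, and 120 probe sets were lower in the second cycle. The limma interaction of cycle and rhythm passed for 2 probe sets that do not carry exactly 1 gene symbol, with 48 at an unadjusted p under 0.05. Both had smaller amplitudes in the second cycle, 0.36 after 1.15 and 0.39 after 1.22 log2, each with a limma adjusted p of 0.0456. With the array batch as a block 10 passed. The count changed by over 1.5 times without any single array except 24h replicate 1, 36h replicate 2, 40h replicate 2 and 52h replicate 2, over a range of 0 to 18. On the replicate 2 arrays alone, where 31 probe sets were rhythmic, the median ratio over these was 0.902.

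The period could be read from few probe sets. Of the 5 that differed between times, all had at least 50% of their variance explained, and their best periods on a grid from 18 to 30 h had a median of 25.5 h, with quartiles of 23.75 and 30 h and 2 at the edge of the grid. With the array batch as a block, 33 probe sets gave a median of 24 h, with quartiles of 23.5 and 26 h and 8 at the edge of the grid. The best periods of the 2 probe sets of LHY lay at opposite edges of the grid, 18 and 30 h, so that no period could be read from them. Genes are not independent in these medians.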

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

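The tests of the array batches and of exchanged arrays, and those of the order and the split with the most calls, were chosen only after the results were seen, and the covariates and the periods beyond 22 and 26 h were added after the data were first examined, before their own results were seen.

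Of 52 groups of 4 or 6 arrays, 2 held an array far from the others, where chance gives about 1 in 20. ATPC at subjective dusk had 7.02 log2 in 60h replicate 1 and 6.68 to 6.70 in the other 3 arrays, a gap of 0.941 of the range. RCA14 at subjective midday had 6.99 log2 in 56h replicate 1 and 6.47 to 6.55 in the other 3 arrays, a gap of 0.845 of the range. The cycles differed by the interaction test for 2 probe sets that do not carry exactly 1 gene symbol, each with a limma adjusted p of 0.0456. Their amplitudes were 1.15 and then 0.36 log2 in one, and 1.22 and then 0.39 in the other.

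The rhythm of 138 probe sets on one axis of peak times stood out. Of 100 orders of the 13 times, the real one included, 4 gave as many probe sets, narrowly under the threshold of 5% set beforehand. With only 100 orders this share is imprecise and lies close to the threshold, so chance is not firmly excluded. The highest other order gave 622 calls, several times the real count, which points to a structure of the samples. Of these 622 calls 18 were among the 138. With the mean of the maturation list as a covariate that order gave 0 calls, and with the array median 468, so its calls went with the maturation mean. With the mean of the maturation list as a covariate the median ratio of amplitudes was 0.917 and 127 of the 138 calls were kept, and with the array median as a covariate the ratio was 1.02, which argues against either as the whole cause. Periods of 16 to 20 and 28 to 36 h gave at most 4 calls, while 22 h gave 64 and 26 h 112, so a cycle of 22 to 26 h stays open. A clock-driven rhythm stays a hypothesis; it was not tested apart from these explanations.

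Calls appeared within the high floor arrays (42) and not within the low floor arrays (0), a difference that was not itself tested. At an unadjusted p under 0.05 the high floor arrays gave 1509 probe sets and the low floor arrays 554, where chance alone gives 574. The median ratio of amplitudes, low over high floor, was 0.943, with quartiles of 0.739 and 1.2, but these probe sets were chosen on both batches together. Of the 42 chosen on the high floor arrays alone, 40 had the same sign in the low floor arrays at the same phase, against 58% of all tested, which argues against a rhythm absent from the low floor arrays. Their median ratio was 0.592 (quartiles 0.481 and 0.699); choosing on the high floor arrays raises the amplitude there and lowers this ratio, so whether the rhythm was smaller in the low floor arrays stays open. The median ratio of residual SDs was 1.16, with quartiles of 0.941 and 1.37, so that a larger spread in the low floor arrays stays open. No biological explanation was tested, since each batch held 1 array of every time.

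The smaller amplitude in the second cycle, with a ratio of 0.580, has chance open: 4 of 32 exchanges of the cycles at the 6 phases gave as large a change, and the largest change among the others was a ratio of 0.538 or its inverse. A single array is argued against, as the ratio stayed at most 0.638 whichever array was left out. An exchange of the 48 and 56 h arrays of the low floor batch would raise the calls from 138 to 248, and 2 of 78 such exchanges gave as many, the highest other 250. More calls than the 138 came from 18 of the 78, and the low floor arrays alone still gave 0 under that exchange, which weighs against it. The ratio under that exchange was 0.584, so it would not account for the smaller amplitude, and whether any arrays were exchanged stays open. A loss of rhythm in constant light is a biological explanation the design allows, and it was not tested.

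For subjective dawn against dusk, 31 of 100 splits of the 10 arrays gave as many probe sets at an unadjusted p under 0.05 as the real split in a fit of these 10 arrays, 658. The real split is balanced for the array batch, while the other splits were not held to this and the fit had no batch term. The comparison therefore cannot decide on chance, which stays open. The highest count of another split was 2672, which points to a structure of the samples. The split with 2672 had 2 low floor arrays among its 6 and 3 among its 4, with means of the maturation list of 11.74 and 11.92 log2. Its array medians averaged 6.38 and 6.21 log2, the widest difference of the 100 splits. With the array median as a covariate it gave 410 probe sets. As that covariate was tied to the split, it would lower the count whatever the cause, so the drop cannot be put down to the array-wide level. Over the 100 splits the count rose with the difference of array medians (Spearman rho 0.716). The real split gave 945 with that covariate, under which the other 98 splits were not run.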

How the results depend on the processing

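The array batch as a block, each array batch alone, periods of 16 to 20 and 28 to 36 h and the covariates were chosen after seeing the data. So were the replicate block for lists and peak times, 1 probe set per probe cluster and the count without shared probe sets. The lists by symbol were written after the values and the symbols had been looked at. The cause of the changes below was not tested except where fewer arrays or probe sets entered the test. The 24 h rhythm, 138 probe sets, gave 76 with no filter on low values, 232 after another quantile normalization, 258 with no linear time term, 264 with the array median as a covariate, 64 at a period of 22 h, 0 at 16, 18, 20, 30, 32 and 36 h, 4 at 28 h, 28 with 24 h and 12 h harmonics, 83 at a change of at least 1.5 times, 77 without probe sets marked as shared, 0 in the low floor and 42 in the high floor arrays. Leaving out arrays, 1 at a time or all of a replicate number, gave 0 to 199. Core clock genes gave 0 throughout. Any difference between times, 5 probe sets, gave 0 with no filter, 31 at a mean log2 above 6, 79 after quantile normalization, 93 after median centring, 60 with a trended and robust eBayes, 35 with the array batch block and 0 to 59 with arrays left out. The linear trend, 0, gave 3 without 24 h terms and 0 to 1 with arrays left out, and dawn against dusk, 0, gave 0 to 1. Enriched fixed lists, 0, were 1 at a mean log2 above 6, 1 with the array batch block and 0 to 1 with arrays left out. Enriched lists by symbol, 1, were 0 at a threshold of 0.01, 0 with 1 probe set per probe cluster and 0 to 3 with arrays left out; the rhythmic probe sets of the chloroplast list, 6, were 2 at a threshold of 0.01 and 0 to 8. The share of peaks in the midnight bin, 79.7%, was 94.1% at a threshold of 0.01 and 67.7% to 87.2% with arrays left out. Camera calls for dawn against dusk, 2 fixed lists and 2 by symbol, were 0 and 0 with an estimated correlation, and with an array left out reached 3 and 2 to 7. The cycle interaction, 2, was 10 with the array batch block and 0 to 18 with arrays left out, and the ratio of amplitudes was 0.531 to 0.902. The period, 25.5 h, was 23.75 h on a grid of 20 to 28 h, 24 h with the array batch block and 23.5 to 30 h with arrays left out. Of the alternatives for the named rhythmic genes, 260 kept the call and 112 lost it, and 0 turned the phase.

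Replicate numbers gave little sign of pairing the samples. The correlation of deviations from the time means had a median of 0.022 over pairs with the same number and a lowest of -0.38, with 43.6% above 0.1. Over pairs of the same array batch the median was 0.142 and the lowest -0.34, with 57.7% above 0.1, so deviations went somewhat more with the array batch. With the replicate block the 24 h rhythm gave 144, the linear trend 1, any difference between times 12, the cycle interaction 8 and the chloroplast list 7; enriched lists, camera calls, core clock genes and dawn against dusk kept their counts. The period and the named genes were not run with this block. The planned test of probe sets of other organisms was not run, as the table used here held none. Weak signals limit what could be seen: LHY averaged 4.63 log2, near the filter of 4.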

Other observations

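The tests of this part were chosen only after the spread of single maturation genes had been seen. Genes of seed maturation and desiccation tolerance varied widely between the replicates of one time while giving no rhythm that passed. MAT1 ranged from 4.61 to 10.16 log2 over the 26 arrays, with a within-time SD of 1.16. MP2 had a within-time SD of 0.68, PM13 of 0.62, PM3 of 0.50, SLE2 of 0.47 and PM22 of 0.42, and the limma adjusted p of their rhythms lay between 0.520 for PM13 and 0.968 for PM22. The median within-time SD of the 32 maturation probe sets was 0.26 log2, above the medians of all 10000 random lists matched on mean signal (percentile 100), whose own median was 0.14. Random lists lack the correlation between the maturation genes, estimated at 0.446 for the dawn and dusk contrast. This percentile and the one below may therefore be too high. The medians of all tested probe sets and of the chloroplast list, not matched on signal, were both 0.21. With the array median as a covariate the maturation list had 0.21, all tested probe sets 0.19 and the random lists 0.13 (percentile 100 of 10000 again), which argues against the array-wide level as the whole cause; part of the spread went with it, as differences of the maturation mean and of the array median between the arrays of a time had r = -0.613. One hypothesis is that seeds of one time may have differed in maturity although flowers were marked at opening.

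Whether the mean of the maturation list goes with the contrast of late-night and midday rhythmic genes stays open, since the relation did not pass within times, among 6 computed. Over differences between the arrays of each of the 13 times Pearson r was -0.605 (permutation p = 0.0266, adjusted 0.0532) and Spearman rho -0.478 (permutation p = 0.101, adjusted 0.101). Over the 26 arrays, which the permutation treats as exchangeable although the contrast depends on time, r was -0.546 (permutation p = 0.00466, adjusted 0.0140) and rho -0.559 (permutation p = 0.00366, adjusted 0.0140). Without the 2 arrays farthest from the median of the maturation mean r was -0.585. Within the low floor arrays r was -0.531 (permutation p = 0.0625, adjusted 0.0750) and within the high floor arrays -0.549 (permutation p = 0.0554, adjusted 0.0750).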
